A study of Danio rerio with 18 samples.

How the data were processed

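RNA was measured on 18 Affymetrix zebrafish arrays from embryos at 52 hours post fertilization. The arrays fall into 6 groups of 3: wild type and young mutants, which carry a mutation in smarca4 (smarca4a in the present gene table), each as whole embryos, dissected retinas, and retinas with the retinal pigment epithelium (RPE) still attached. Each array held a pool, of 10 embryos or tissues in most groups, 9 in mutant retina replicate 2 and 6 in each mutant RPE-attached pool. Pools are labelled as independent replicates, and the limma p-values of single genes measure only the spread between such pools; tests of lists and of sets compare genes, which are not independent. The number of arrays limits the precision of each value.

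The deposited values are on the log2 scale, as the authors made them with the robust multiarray average. The submitters' processing notes name RMA, the package affy and R 2.2.0; the version of affy is not given in the sources used here. The raw scans were not used here. The table held 15617 probe sets, of which 115 control probe sets were left out of the tests and 15502 were tested. Of these, 10795 had 1 gene symbol, 135 had several and 4572 had none, and the named probe sets covered 8793 genes. Symbols came from the platform annotation, brought up to date through the Entrez identifier for 1 probe set and kept as given for 84 whose identifier was not in the gene table of assembly GRCz12tu. That assembly served for names and for neighbouring genes only. A gene was represented by its probe set with the highest mean over all arrays.

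Differences were tested in limma 3.58.1 under R 4.3.3, with a mean for each of the 6 groups over all 18 arrays, empirical Bayes moderation and Benjamini-Hochberg adjustment over the probe sets tested. A probe set was called at an adjusted p under 0.05, and the 0.001 threshold of the series design is given beside it. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The comparisons were mutant against wild type in retina, in RPE-attached retina and in whole embryo; RPE-attached against bare retina in each genotype; the difference of that contrast between genotypes; the difference of the genotype effect between retina and whole embryo; and wild type retina against whole embryo. The submitters estimated RPE values by a method that is not given in the sources used here, so RPE-attached pools were compared with bare retina directly. Combined selections took genes called in each of a pair of comparisons.

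Gene lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 23 lists of a comparison. An estimated correlation and fry were alternatives. The lists were melanin synthesis and melanosome; RPE visual cycle and function; retinal progenitor and ciliary margin; photoreceptor; ganglion cell; amacrine and horizontal cell; bipolar and Muller cell; synaptic vesicle; DNA replication; mitosis; p53 targets and apoptosis; lens, muscle, erythrocyte and endothelium; macrophage and leukocyte; mesenchyme, cartilage and collagen; iridophore, xanthophore and neural crest pigment cell; epidermis and cornea; yolk and liver; the SWI/SNF complex; stress and immediate early genes; and Notch and proneural genes. They hold 1111 entries, of which 693 were on the array, and some genes stand in more than 1 list. The tests, thresholds, lists, most alternatives and the rule for naming genes were fixed before the data were examined. That rule took smarca4a in every comparison, the 8 largest called changes in each direction among genes with established symbols whose arrays did not overlap between the groups (the overlap was not asked of the differences between contrasts), up to 4 members of each list with the smallest p-value, and the 10 largest members of each combined selection. The text uses fewer, and says where a gene was chosen otherwise.

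Replicate numbers are not stated to pair samples, so no block was used. A check across probe sets found that arrays with the same number deviated together among the embryo and retina groups: for all 6 pairs of those groups the correlations across genes ran from 0.29 to 0.60, with genes not independent of one another. In pairs with an RPE-attached group they ran from -0.20 to 0.16. A block for replicate number over the 12 embryo and retina arrays was therefore added as an alternative after the data were seen, and is given where it changed a count by more than 1.5 times. The labels give no scan date or array batch.

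The other alternatives were the 0.001 threshold, a minimum of 2-fold, leaving out probe sets under the 30th percentile of group means (a log2 signal of 5.15), testing 1 probe set per gene, quantile normalization again, subtraction of array medians, trended and robust moderation, array weights, the compared groups alone, the replicate number as a block over all arrays, and leaving out each array in turn. Fits without the RPE-attached arrays, an interaction on linear signal and an interaction over the probe sets higher in wild type RPE-attached retina were further ones.

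The method was tested on simulated data with 15502 probe sets, of which 200 were changed. For a retina comparison it recovered 46.3% of changes of 0.5, 92.5% of changes of 1 and 100% of changes of 2 (log2), with 7 false calls among 166. For the genotype difference of the RPE-attached contrast it recovered 11.9%, 77.6% and 100%, with 6 false calls among 132. A simulated shift of -0.5 in the ganglion cell list was called, and of the 22 other lists 0 were called. The combined selections were also counted in 20 simulations without an interaction and in 20 with a mutant retina set equal to wild type.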

Results

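Gene expression was profiled at 52 hours post fertilization in zebrafish embryos, retinas and retinas with attached RPE, in wild type and in the young mutant, which carries a mutation in the chromatin remodelling ATPase Smarca4. The series set out to find genes that depend on Smarca4 in the retina and in the RPE, the pigmented layer behind it. Each of the 6 groups had 3 arrays, each from a separate pool. Within a group, array correlations across genes ran from 0.987 to 0.996, with the lowest values in mutant RPE-attached retina, where the median SD per gene was 0.175 against 0.111 to 0.123 in the other groups. Values are log2 signals. Changes are log2 differences ± SE, with n = 3 arrays per group. Each SE comes from the moderated variance of the fit over all groups, so it does not give the spread of the compared groups alone. Fold is given as a ratio above 1 in the direction stated. No fold is given for a gene whose lower group had a signal under 5.15, the 30th percentile of group means, since background limits the size of such a change.

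smarca4a itself was lower in mutants in every tissue. Its brighter probe set fell from 11.15 ± 0.16 to 8.89 ± 0.20 (SD, n = 3) in retina, from 10.84 ± 0.28 to 9.20 ± 0.28 in RPE-attached retina and from 10.30 ± 0.14 to 7.87 ± 0.14 in whole embryos. These are falls of 4.79-fold, 3.12-fold and 5.38-fold, with limma adjusted p of 1.6e-09, 8.0e-08 and 3.9e-09. A further smarca4a probe set fell as well, with changes of -1.55, -1.28 and -1.64. The size of the fall was not called different between retina and RPE-attached retina (0.62 ± 0.22, adjusted p = 0.0531).

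**Figure D1:**
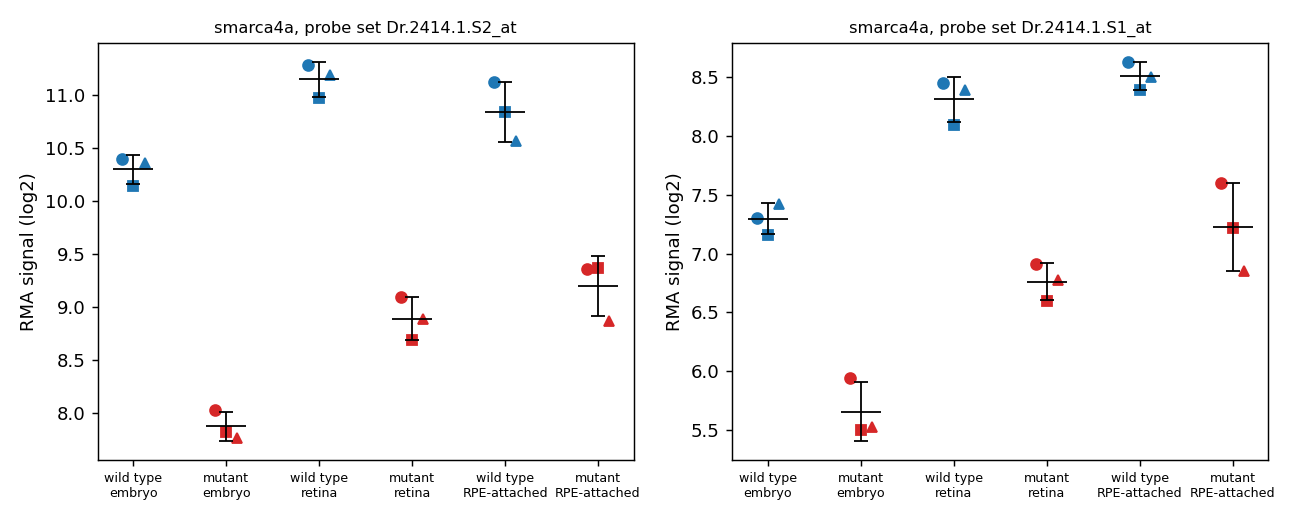
Log2 signal of smarca4a (vertical axis) in the 6 groups. Each point is an array (circle, square and triangle are replicates 1, 2 and 3; blue wild type, red mutant) and black bars give mean ± SD; wild type retina had a mean of 11.15 and mutant retina 8.89.

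The first comparison asked what changes in the mutant retina. Among the largest falls were genes of differentiated retinal cells. calb2b, a calcium-binding protein of amacrine and ganglion cells, fell 18.7-fold (-4.23 ± 0.14, adjusted p = 1.5e-13), rlbp1a, the retinaldehyde-binding protein of Muller glia, fell 8.74-fold (-3.13 ± 0.10), and syt1a, a calcium sensor for vesicle release, fell 8.34-fold (-3.06 ± 0.12). Genes of dividing cells rose, such as cdc25b, a phosphatase that drives entry into mitosis, by 2.63-fold (1.39 ± 0.20). ascl1a, a proneural factor, rose by 3.14-fold (1.65 ± 0.14) and sox21b by 4.96-fold (2.31 ± 0.17), while progenitor genes as a list were not called. The largest rise was that of atf5a, a stress-response transcription factor (2.77 ± 0.31).

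Of 22 ganglion cell genes measured, 0 rose, 19 fell and 3 were not called (1 and 19 when adjusted over the list alone; median -1.10, camera adjusted p = 2.1e-21). Among them were irx4a (-2.83), the intermediate filament gene inab (-2.61), the microtubule regulator stmn2a (-2.17) and the axon growth protein gap43 (-2.05). Of 25 amacrine and horizontal cell genes, 1 rose and 16 fell (1 and 18 adjusted over the list alone; median -1.12, adjusted p = 1.7e-17), with slc32a1, the vesicular GABA transporter, at -2.66. Of 17 synaptic vesicle genes, 1 rose and 13 fell (1 and 13 over the list alone; median -0.77, adjusted p = 2.2e-11). Of 20 bipolar and Muller cell genes, 2 rose and 9 fell (2 and 10 over the list alone; median -0.19, adjusted p = 6.3e-04). All 4 of these lists were also called with an estimated correlation.

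Fewer photoreceptor genes were bright enough to fall far: 23 of 36 had a wild type retina signal above 5.15, against 20 of 22 ganglion cell genes. Whether photoreceptor genes moved less than the other lists was not tested. Of 36 measured, 3 rose, 10 fell and 23 were not called (the same counts adjusted over the list alone; median -0.07, camera adjusted p = 0.0267). Those that fell included the calcium sensor rcvrn2 (-2.27), the phosphodiesterase subunit pde6ha (-1.68) and the transducin subunit gngt1 (-1.40). The call of the list was lost with an estimated correlation (adjusted p = 0.212 with an estimated correlation) and without mutant retina replicate 1 (adjusted p = 0.083, against 0.00825 as the lowest without any other array).

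Of 40 mitosis genes, 30 rose and 0 fell (35 and 0 adjusted over the list alone; median 0.54, camera adjusted p = 7.6e-15), and of 45 DNA replication genes, 27 rose and 0 fell (30 and 0 over the list alone; median 0.44, adjusted p = 1.4e-11). With an estimated correlation the mitosis call held, and the replication call was lost (adjusted p = 0.11 with an estimated correlation). Single changes were modest: cdc6, which loads the replicative helicase, rose 1.82-fold, and the centriole kinase plk4 rose 1.81-fold. Of 44 Notch and proneural genes, 16 rose and 5 fell (19 and 6 over the list alone; median 0.23, adjusted p = 0.0112; adjusted p = 0.172 with an estimated correlation); the Notch ligand dlc rose by 1.31 and insm1b by 1.34, and neurod6a fell (-2.33).

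Several other lists changed in both directions or held few calls in retina. Of 30 progenitor and ciliary margin genes, 9 rose and 6 fell (adjusted p = 0.698), with foxn4 at 1.24 and sox3 at 1.06 among the risers and meis1b at -1.02. Of 32 p53 and apoptosis genes, 8 rose and 4 fell (adjusted p = 0.606); rps27l rose by 0.99 while tp53inp1 (-1.53) and phlda3 (-1.16) fell. Of 47 stress and immediate early genes, 12 rose and 7 fell (13 and 8 adjusted over the list alone), with ier5l at 1.57 and junba at -2.68. Of 17 SWI/SNF complex genes, arid2 (0.68) and bicra (0.69) rose and smarca4a fell. Of 12 lens genes, 3 rose and 0 fell (adjusted p = 0.0579), namely crybb1 (2.60 ± 0.53), cryba4 (2.41 ± 0.44) and crygmxl2 (2.28 ± 0.37), all lens crystallins. Their SDs were 1.46, 1.51 and 1.34 in mutant retina and 0.19, 0.21 and 0.14 in wild type retina (n = 3). The SEs given pool this spread with that of the other groups. In mutant retina replicate 3 the median of these crystallins lay 0.58 above the highest wild type array, against 3.09 and 3.04 in replicates 1 and 2.

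In total 2834 of 15502 probe sets were called in retina, 1376 higher and 1458 lower in the mutant, or 888 and 835 of 8793 genes. At the 0.001 threshold 1201 were called, 478 higher and 723 lower, and with at least 2-fold 158 were higher and 449 lower. With the replicate number as a block over the embryo and retina arrays, chosen after the data were seen, 4807 were called.

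**Figure D2:**
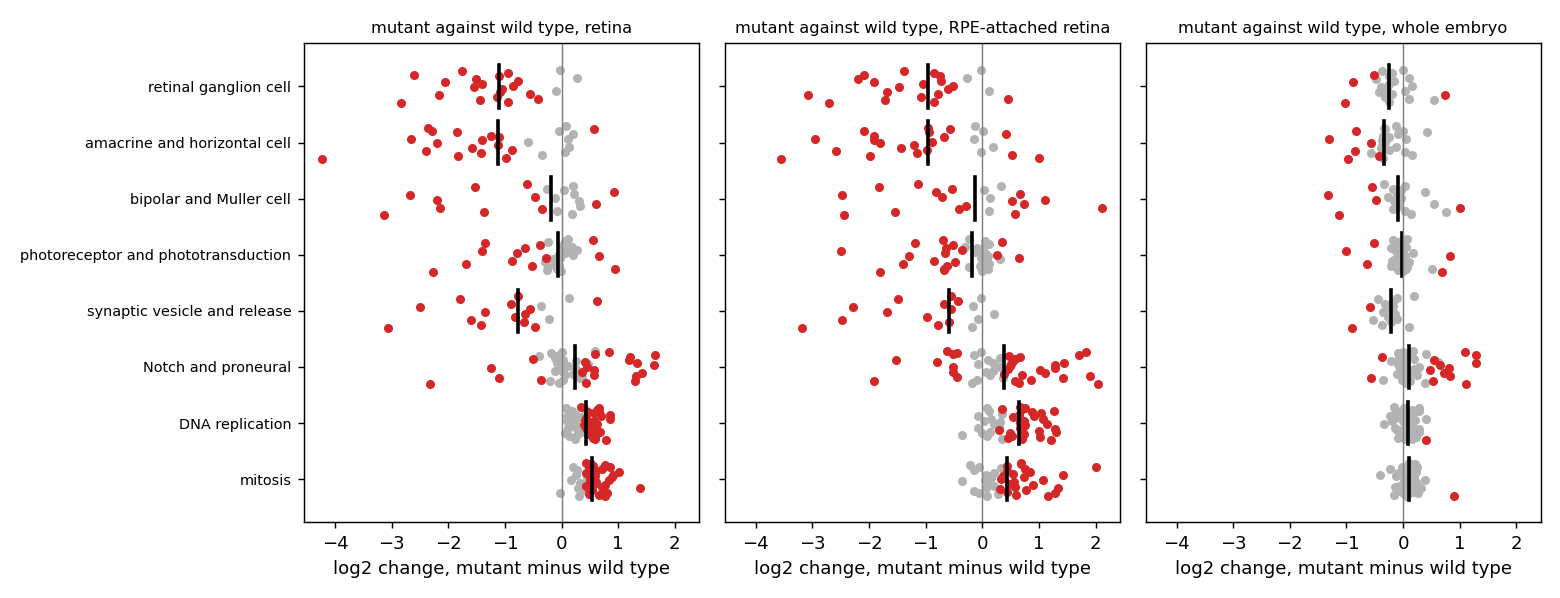
Log2 change, mutant minus wild type (horizontal axis), of the measured members of 8 gene lists in retina, RPE-attached retina and whole embryo. Each point is a gene (red, adjusted p under 0.05; grey, not called) and black lines are list medians, which for ganglion cell genes were -1.10, -0.95 and -0.24.

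In RPE-attached retina, neuronal genes again fell in the mutant, with the ganglion cell and the amacrine and horizontal cell lists called. calb2b fell 11.7-fold (-3.55 ± 0.14), syt1a 9.10-fold (-3.19 ± 0.12), inab 8.38-fold (-3.07 ± 0.16) and crabp1a, a retinoic acid binding protein, 7.04-fold (-2.82 ± 0.15). The DNA repair gene xrcc1 rose by 2.65 ± 0.16, the growth factor mdkb 4.33-fold (2.11 ± 0.17), sox11b 4.11-fold (2.04 ± 0.12) and ascl1a 3.74-fold (1.90 ± 0.14). Some pigment genes rose, though the melanin list was not called: pmelb, which builds the melanosome scaffold, by 0.86 ± 0.21, dct, an enzyme of melanin synthesis, by 0.55 ± 0.15 and mitfb, a regulator of pigment cells, by 0.41 ± 0.11. Mean signals of other attached tissue differed too, from wild type to mutant: crestin (neural crest) 8.31 to 9.84, plvapb (vessels) 7.52 to 8.44 and gch2 (xanthophores) 7.72 to 6.47. A change within the RPE cannot be told apart from a change in the tissue attached.

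Of 22 ganglion cell genes, 1 rose and 18 fell (the same counts adjusted over the list alone; median -0.95, camera adjusted p = 3.3e-11), and of 25 amacrine and horizontal cell genes, 3 rose and 17 fell (median -0.96, adjusted p = 1.5e-08); both lists were also called with an estimated correlation. Of 17 synaptic vesicle genes, 0 rose and 12 fell (adjusted p = 3.0e-06), and of 36 photoreceptor genes, 3 rose and 15 fell (adjusted p = 0.00252); each call was lost, with adjusted p = 0.173 with an estimated correlation. Of 20 bipolar and Muller cell genes, 6 rose and 10 fell, and the list was not called (adjusted p = 0.184). Of 45 DNA replication genes, 30 rose and 0 fell (31 and 1 adjusted over the list alone; adjusted p = 2.4e-07), and of 40 mitosis genes, 24 rose and 0 fell (25 and 0 over the list alone; adjusted p = 2.2e-04); each call was lost, with adjusted p = 0.305 with an estimated correlation. dnmt1, the maintenance DNA methyltransferase, rose by 1.26 and the kinetochore gene ndc80 by 1.42. Of 14 melanin genes, 6 rose and 1 fell (adjusted p = 0.66), and of 17 RPE genes, 5 rose and 2 fell (adjusted p = 0.736); neither list was called. vegfaa, an angiogenic factor, rose by 1.21.

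Called probe sets numbered 7274, of which 4139 were higher and 3135 lower in the mutant, and 3328 at the 0.001 threshold. With at least 2-fold the balance turned, to 576 higher and 610 lower. Mutant RPE-attached arrays varied most (median SD 0.175), so a spread shared over all groups understates the error of comparisons with them. Fitting only the compared groups called 6222, and array weights 6138. Control probe sets differed between the RPE-attached groups. Hybridization controls, which are added in fixed amounts, averaged 11.15 ± 0.15 (SD, n = 3) in mutant RPE-attached retina against 9.46 ± 0.05 in wild type RPE-attached retina and 9.55 to 9.78 in the 4 other groups. Poly-A controls, which are added before labelling, averaged 5.61 ± 0.19 in mutant and 7.77 ± 0.09 in wild type RPE-attached retina against 6.29 to 6.64 elsewhere. No scan date is given, so each RPE-attached group and its array run cannot be told apart. Each pool held 6 tissues in mutant and 10 in wild type RPE-attached retina, so genotype and pool size cannot be told apart either.

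**Figure D3:**
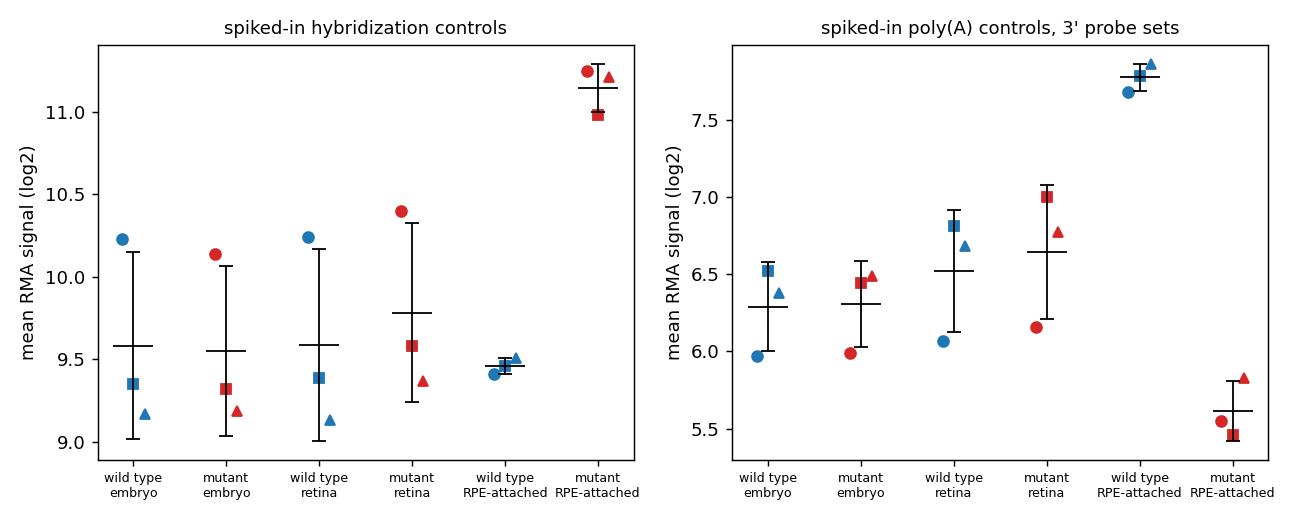
Mean log2 signal of control probe sets (vertical axis) on each array by group; circle, square and triangle are replicates 1, 2 and 3, blue is wild type, red is mutant, and black bars give mean ± SD. Hybridization controls averaged 11.15 in mutant RPE-attached retina and 9.46 in its wild type counterpart.

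In whole embryos the mutation changed genes outside the eye as well. anxa1b, an annexin of the epidermis, fell 13.1-fold (-3.71 ± 0.22, adjusted p = 3.2e-09), aebp1b fell 5.52-fold (-2.46 ± 0.16) and fkbp5, a glucocorticoid-responsive co-chaperone, 3.80-fold (-1.92 ± 0.24). The collagen gene col28a2a (-2.42 ± 0.12) and uox, which encodes urate oxidase (-1.94 ± 0.12), also fell. mmp9, a matrix metalloprotease of leukocytes, rose 3.82-fold (1.93 ± 0.16), the globin gene hbaa1 2.92-fold (1.54 ± 0.19), and xrcc1 by 1.69 ± 0.16.

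Neuronal lists fell here too, by less: of 25 amacrine and horizontal cell genes, 0 rose and 6 fell (1 and 11 adjusted over the list alone; median -0.33, camera adjusted p = 1.4e-07), and of 22 ganglion cell genes, 1 rose and 3 fell (2 and 6 over the list alone; median -0.24, adjusted p = 0.00171). Both were also called with an estimated correlation. Of 22 erythrocyte genes, 6 rose and 0 fell (10 and 0 over the list alone; median 0.30, adjusted p = 5.1e-07; adjusted p = 0.0762 with an estimated correlation, so the call was lost), among them urod, an enzyme of heme synthesis (0.64), and epb41b, a gene of the red cell skeleton (0.83). Of 44 Notch and proneural genes, 11 rose and 2 fell (adjusted p = 8.0e-05; adjusted p = 0.0541 with an estimated correlation), with hes6 at 1.28. Of 47 stress and immediate early genes, 7 rose and 2 fell (adjusted p = 0.00201; adjusted p = 0.115 with an estimated correlation), with socs3b at 1.13, and of 34 macrophage genes, 7 rose and 1 fell (adjusted p = 0.00228; adjusted p = 0.0919 with an estimated correlation). Of 17 synaptic vesicle genes 0 rose and 2 fell (adjusted p = 8.9e-04; adjusted p = 0.291 with an estimated correlation). Mitosis and DNA replication genes each had 1 riser, with adjusted p = 0.0857 and adjusted p = 0.159.

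In embryos 1044 probe sets were called, 526 higher and 518 lower in mutants, and 260 at the 0.001 threshold. With at least 2-fold, 54 were higher and 94 lower. The block over the embryo and retina arrays called 2525.

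Genes called in the same direction in all 3 mutant comparisons numbered 245, of which 126 were higher and 119 lower, against 9.34 and 6.51 for independent lists of the same sizes. RPE-attached pools hold the retina, and whole embryos hold the eye, so independent lists were not to be expected. The excess does not show an effect shared by separate tissues. crabp1a fell in each (-2.52, -2.82 and -1.74 in retina, RPE-attached retina and embryo), and mybl1, a cell cycle transcription factor, rose in each (1.75, 2.05 and 1.72), as did xrcc1 (1.92, 2.65 and 1.69). Retina and RPE-attached retina shared 603 of the genes that rose and 585 of those that fell.

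Whether the fall of neuronal genes is stronger in the retina than in the embryo as a whole was tested as a difference of genotype effects. calb2b fell further in retina (-2.91 ± 0.20), as did junba, an immediate early gene (-2.95 ± 0.29), syt1a (-2.15 ± 0.17) and rlbp1a (-2.00 ± 0.14). The effect in retina was higher than in embryos for sox21b (2.29 ± 0.24). Of 22 ganglion cell genes, 0 differed upward and 15 downward (0 and 19 adjusted over the list alone; median -0.98, camera adjusted p = 2.7e-24), of 25 amacrine and horizontal cell genes, 1 and 13 (adjusted p = 3.4e-15), and of 40 mitosis genes, 6 and 0 (21 and 0 over the list alone; median 0.49, adjusted p = 7.0e-13). These 3 lists were also called with an estimated correlation. Called probe sets numbered 1067, 374 above 0 and 693 below, 378 at the 0.001 threshold, and 2314 with the block over these 12 arrays.

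RPE genes were enriched in the RPE-attached pools of wild type fish. rpe65a, the isomerase of the visual cycle, was 10.5-fold higher than in bare retina (3.39 ± 0.18, adjusted p = 1.3e-09). pmelb was 7.27-fold higher (2.86 ± 0.21), dct 5.90-fold (2.56 ± 0.15), stra6, the receptor for retinol-binding protein, 4.56-fold (2.19 ± 0.17) and rgrb, a retinal G protein-coupled receptor of the RPE, 3.89-fold (1.96 ± 0.15). Genes of other tissues behind the retina were higher too: gch2, a pteridine enzyme of xanthophores (2.90 ± 0.31), the neural crest marker crestin (2.00 ± 0.14), the cartilage collagen col2a1a (1.70 ± 0.21) and the vessel gene plvapb (0.89 ± 0.11).

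Of 14 melanin genes, 7 were higher and 1 lower (8 and 1 adjusted over the list alone; median 0.33, camera adjusted p = 1.8e-04), and of 17 RPE genes, 7 and 0 (the same over the list alone; median 0.13, adjusted p = 0.00128). Of 47 mesenchyme and cartilage genes, 28 were higher and 0 lower (31 and 0 over the list alone; median 0.44, adjusted p = 1.5e-10), of 16 endothelial genes, 12 and 1 (adjusted p = 7.0e-04), and of 17 iridophore and xanthophore genes, 10 and 1 (adjusted p = 2.0e-05). All 5 lists were also called with an estimated correlation. Muscle genes (12 of 42 higher, 0 lower, adjusted p = 0.00183), epidermis genes (10 of 42, 0 lower, adjusted p = 0.00427) and macrophage genes (8 of 34, 1 lower, adjusted p = 0.00587) lost their calls, with adjusted p = 0.394, 0.428 and 0.103 with an estimated correlation. Of 25 amacrine and horizontal cell genes, 2 were higher and 11 lower (median -0.27, adjusted p = 0.0296; adjusted p = 0.0651 with an estimated correlation). In this comparison 4533 probe sets were called, 2361 higher and 2172 lower, and 1128 at the 0.001 threshold. The share that was higher, 52.1%, became 36.1% when array medians were subtracted, and with at least 2-fold 94 were higher and 114 lower. Fitting only the compared groups called 5322 probe sets, and array weights 5542.

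**Figure D4:**
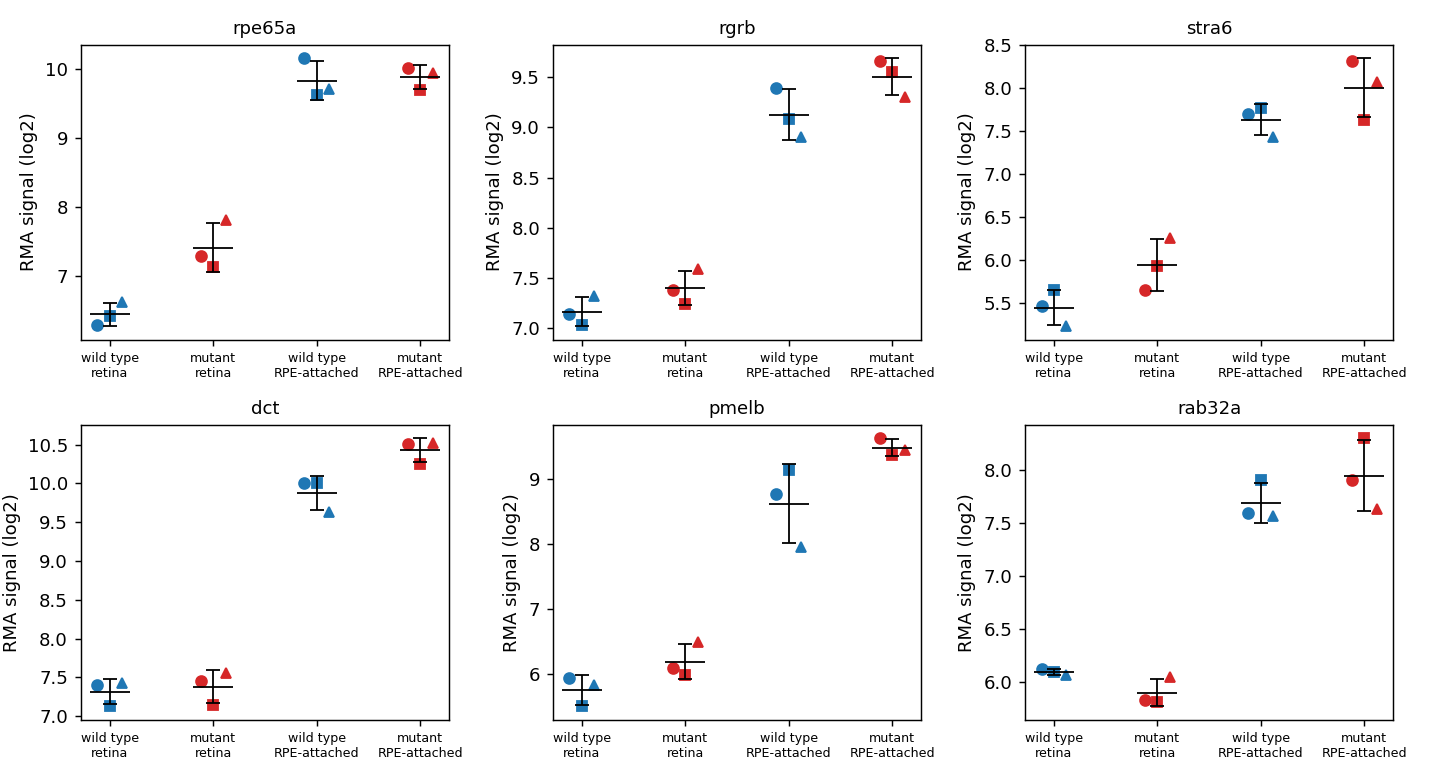
Log2 signal (vertical axis) of rpe65a, rgrb, stra6, dct, pmelb and rab32a in bare and RPE-attached retina of wild type (blue) and mutant (red) fish. Circle, square and triangle are replicates 1, 2 and 3, and black bars give mean ± SD; rpe65a averaged 9.83 in wild type and 9.88 in mutant RPE-attached retina.

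RPE and pigment genes were also higher in mutant RPE-attached pools than in mutant retina. crestin was 10.9-fold higher (3.45 ± 0.14), pmelb 9.79-fold (3.29 ± 0.21), dct 8.24-fold (3.04 ± 0.15), rpe65a 5.55-fold (2.47 ± 0.18), stra6 4.19-fold (2.07 ± 0.17) and rgrb 4.29-fold. Lower were hmgn1b, a nucleosome-binding protein (-2.69 ± 0.24), cst3, a protease inhibitor (-2.57 ± 0.15), elof1, a transcription elongation factor (-2.47 ± 0.16), and cs, which encodes citrate synthase (-2.45 ± 0.23). Of 14 melanin genes, 7 were higher and 0 lower (10 and 0 adjusted over the list alone; median 0.57, camera adjusted p = 4.9e-04), and of 16 endothelial genes, 8 and 0 (adjusted p = 0.00506); both calls held with an estimated correlation. Of 17 RPE genes, 9 were higher and 1 lower (10 and 1 over the list alone; adjusted p = 0.00973; adjusted p = 0.0991 with an estimated correlation), and of 47 mesenchyme and cartilage genes, 29 and 0 (adjusted p = 2.5e-08; adjusted p = 0.0527 with an estimated correlation). The lens list had a median of 0.20 and a mean of -0.34. Of all probe sets, 6240 were called, 3708 higher and 2532 lower, and 2259 at the 0.001 threshold. The share that was higher, 59.4%, became 46.8% when array medians were subtracted, and with at least 2-fold 256 were higher and 420 lower. Fitting only the compared groups called 4641 probe sets, and array weights 5198.

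The difference of these contrasts asks which genes of the RPE-attached layer depend on the genotype. The enrichment of rpe65a was smaller in mutants (difference -0.92 ± 0.26, adjusted p = 0.0164). It averaged 9.83 ± 0.29 in wild type and 9.88 ± 0.17 in mutant RPE-attached pools (SD, n = 3), and 6.44 ± 0.17 and 7.41 ± 0.36 in bare retina, where it rose by 0.97 ± 0.18 (adjusted p = 5.2e-04). A dimmer rpe65a probe set showed no call for the difference (-0.05 ± 0.22, adjusted p = 0.903). Without wild type RPE-attached replicate 1 the difference was -0.75 and no longer called (adjusted p = 0.051), and on linear signal it was not called either. slc24a4a, a cation exchanger of the melanin list, was more enriched in mutants (0.74 ± 0.16), as were crestin (1.44 ± 0.19) and plvapb (1.31 ± 0.15). The difference of crabp2a, a retinoic acid binding protein, was -0.91 ± 0.18, with means of 9.80 in bare and 9.87 in RPE-attached retina in wild type, and 11.05 and 10.21 in mutants. Among the largest differences were those of hmgn1b (-3.23 ± 0.35) and mdkb (2.73 ± 0.24).

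Of 14 melanin genes, 1 differed upward and 0 downward, and of 17 RPE genes, 2 and 2 (1 and 0, and 2 and 2, adjusted over the list alone). No list was called, the lowest camera adjusted p being 0.438 and the lowest with an estimated correlation 0.924. Called probe sets numbered 3128, of which 1793 were above 0 and 1335 below, and 424 at the 0.001 threshold. After quantile normalization again, 1598 were above 0 and 1612 below. Fitting only the compared groups called 2851, and array weights 2789.

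Of 1351 genes higher in wild type RPE-attached than bare retina, 286 had a difference below 0 and 52 above 0. Independent lists would share 126.14 and 169.16, and the highest counts in 20 simulations without an interaction were 1 and 0. The simulations drew independent noise with the same spread in all groups and held no difference between array runs, so they cannot exclude such a difference. Both steps use the same wild type arrays, so deviations of these arrays, by chance or by run, favour differences below 0. Of these genes, 244 and 35 were not called in retina, which does not show that they were equal there. With the 0.001 threshold in both steps the counts were 17 and 3, among 302 genes higher in wild type RPE-attached retina. Leaving out wild type retina replicate 1 gave 159 and 27, and 139 and 19 among genes not called in retina. The count above 0 was 32 without wild type retina replicate 2 and 32, 30 and 28 without wild type RPE-attached replicates 1, 2 and 3. Among genes not called in retina it was 23 without mutant retina replicate 3 and 21, 19 and 17 without those RPE-attached replicates.

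Wild type retina differed from whole embryo in most genes. Retinal genes were higher: rcvrn2 by 12.6-fold (3.65 ± 0.17), the eye field factors pax6b (3.07 ± 0.12), six6b (2.67 ± 0.12) and rx3 (2.36 ± 0.11), and atoh7, which specifies ganglion cells (2.82 ± 0.14). Genes of muscle and blood plasma were lower: the myosin heavy chain myhz1.3 (-9.56 ± 0.11), the calcium pump atp2a1 (-8.68 ± 0.15) and rbp4, a plasma carrier of retinol (-7.17 ± 0.14). Of 42 muscle genes, 0 were higher and 39 lower (median -5.69, camera adjusted p = 8.3e-32), of 42 epidermis genes, 0 and 39 (adjusted p = 1.1e-28), of 40 yolk and liver genes, 1 and 30 (adjusted p = 7.8e-19), and of 36 photoreceptor genes, 30 and 0 (31 and 0 adjusted over the list alone; median 0.58, adjusted p = 1.2e-05). These 4 lists were also called with an estimated correlation. This comparison called 9935 probe sets, 6901 higher and 3034 lower, and 5683 at the 0.001 threshold. With at least 2-fold the balance turned, to 766 higher and 1657 lower. The median change of all genes was 0.24, and subtracting array medians moved it by 0.11, to 0.36.

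Of 4061 genes higher in wild type retina than in the embryo, 371 fell and 542 rose in mutant retina, against 385.64 and 410.12 for independent lists. The genes that fell were thus no more than independent lists would share. Counts of 0 in each of 20 simulations with an unchanged mutant retina follow from that setting. Both steps share the wild type retina arrays. With the 0.001 threshold in both steps, 141 fell and 162 rose among 2193 genes higher in retina. With at least 2-fold in both steps the balance turned, to 65 that fell and 20 that rose. Over all probe sets in retina it turned the same way, with 449 lower and 158 higher. Whether the turn is particular to retinal genes was not tested.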

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

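The count of probe sets below the retinal neuron median and the test of crystallins in RPE-attached retina were tests chosen only after the result was seen.

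Several results stand out because the genotype effect differed between tissues by a test of the difference itself. Between the RPE-attached and the retina contrast this held for 3128 probe sets. Among the named genes the difference (log2) was rpe65a -0.92, crabp2a -0.91, slc24a4a 0.74, mdkb 2.73, ccn2a 2.08, hmgn1b -3.23, cs -2.44, crybb1 -2.76, crygmxl2 -2.44, cryba4 -2.43, elof1 -1.87, crestin 1.44, plvapb 1.31, col1a1a 1.43, mrps18b -1.72, hpda -1.53 and notch2 1.40. On linear signal 6 of these 17 were no longer called, namely rpe65a, crybb1, crygmxl2, cryba4, col1a1a and notch2. With array weights crybb1 and cryba4 were not called (adjusted p 0.0501 and 0.0502), nor was rpe65a without wild type RPE-attached replicate 1 (-0.75, adjusted p 0.051). Between retina and whole embryo it held for 1067 probe sets, with anxa1b 3.73, aebp1b 2.58, col28a2a 2.43, sox21b 2.29, arg2 2.51, crybb1 2.83, crygmxl2 2.59, cryba4 2.56, junba -2.95, calb2b -2.91, samsn1a -2.51, irx7 -2.41, stmn2a -1.92, inab -2.15, rlbp1a -2.00 and syt1a -2.15. Of these, crybb1 was not called with trended and robust moderation (adjusted p 0.081), and crybb1 and cryba4 were not when only the compared groups were fitted (0.0777 and 0.0544). crybb1 was not called either without wild type embryo replicate 3 (0.0633), mutant embryo replicate 2 (0.0616), mutant retina replicates 1 (0.0744) and 2 (0.0716) or wild type retina replicate 1 (0.0547). anxa1b, aebp1b and col28a2a had signals under 5.15, the 30th percentile of group means, in both retina groups (4.95 and 4.98, 4.17 and 4.29, 3.66 and 3.67), so their differences restate the fall in embryos. For crybb1, cryba4 and crygmxl2 both differences mostly restate the variable rise in mutant retina. From wild type to mutant their means were 6.31 and 6.15, 5.85 and 5.84, and 5.75 and 5.59 in RPE-attached retina. In embryos they were 10.46 and 10.24, 11.23 and 11.08, and 11.56 and 11.25. The hybridization controls, which lie outside the measurement of genes, were 1.69 higher in mutant than in wild type RPE-attached retina.

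The first pattern is the many calls in comparisons with the RPE-attached pools. RPE and attached tissue added to an otherwise equal retina as the whole cause is argued against, since 438 called probe sets lay more than 1 (log2) below mutant retina beyond the median of 103 retinal neuron genes (0.01). In wild type, where the same explanation forbids such probe sets too, there were 86 (median -0.05). A difference in the labelling and hybridization run stays open: the deviation of replicate 1, where the hybridization controls were also brighter, correlated across genes with the genotype difference in all 4 embryo and retina groups, with r from 0.16 to 0.26. These correlations are across genes, which are not independent replicates, and they leave most of the difference unaccounted for. The genotype itself stays open as well, because the 3 mutant RPE-attached arrays share a genotype, a tissue, a pool size of 6 and possibly a run.

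The other pattern is the rise of lens crystallins in mutant retina. Crystallin expression of the mutant retina itself is argued against as the whole cause, since RPE-attached pools hold the retina too and crybb1, cryba4 and crygmxl2 there changed by -0.16 ± 0.53, -0.01 ± 0.44 and -0.16 ± 0.37 (median -0.16), each more than 2 standard errors under a rise of 1, though the run of those arrays stays open. Lens tissue left in the mutant pools may account for it: with an added share of 0.199 of whole embryo signal, set by crybb1, 3 further lens genes were predicted to rise by more than 1, and 2 of them rose by more than 0.5. crygmxl2 rose by 2.28 against a predicted 4.00, cryba4 by 2.41 against 3.31, and bfsp2 changed by 0.36 against 1.05, so the test leaves carry-over undecided. Whether 1 pool decides the rise is not settled: 2 of the 3 mutant pools lay more than 1 above the highest wild type pool (3.09 and 3.04), and the other lay 0.58 above it.

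Other splits of the arrays were counted for each number of called probe sets. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05, and in each case 1 split, the real one, gave as many. The real value and the highest of the others were 2834 and 0 in retina, 7274 and 0 in RPE-attached retina, 1044 and 4 in whole embryo, 4533 and 0 for RPE-attached against bare retina in wild type, 6240 and 0 in mutants, and 9935 and 0 for retina against embryo. Every other split mixes the compared groups, which moves the real difference into the spread. Their low counts follow from that structure and give no level for chance. For the differences between tissues, 100 splits were drawn. As many calls as the real 3128 came from 7 of them, the real one included (highest other 6616). All 7 kept or mirrored the real genotypes in a tissue, and the 76 that mixed both tissues gave at most 0. As many as the real 1067 came from 9, the real one included (highest other 1930). All 9 kept or mirrored the real genotypes in a tissue, and the 78 that mixed both gave at most 78. Both shares lie above 0.05, so the counts do not exclude chance by the bound set beforehand. A split that keeps or mirrors a tissue still holds the genotype effect of that tissue, so its high count follows from that structure. These splits therefore do not decide about chance.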

How the results depend on the processing

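The block over the 12 embryo and retina arrays and the fits without RPE-attached arrays were tests chosen after the result was seen. The counts below are in the order retina, RPE-attached retina and embryo (mutant against wild type), RPE-attached against bare retina in wild type and in mutant, the genotype difference of that contrast, retina against embryo genotype effects, and retina against embryo in wild type.

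At an adjusted p under 0.001 the counts were 1201, 3328, 260, 1128, 2259, 424, 378 and 5683, and with at least 2-fold 607, 1186, 148, 208, 676, 545, 478 and 2423; stricter thresholds lower a count by construction. With 1 probe set per gene, 8793 were tested in place of 15502, and the counts were 1754, 4389, 676, 2761, 3796, 1979, 651 and 6074. The block over the embryo and retina arrays gave 4807 in retina, 2525 in embryo and 2314 for the retina against embryo genotype effects; the cause was not tested. Restricted to the 2361 probe sets higher in wild type RPE-attached retina, the genotype difference was called for 636, which follows from fewer probe sets tested. Of these 79 were above 0 and 557 below, a balance that the selection on the shared wild type arrays favours.

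The combined selections are, in order, interaction below 0, above 0, each again among genes not called in retina, and retinal genes lower and higher in mutant retina. At 0.001 they were 17, 3, 17, 3, 141 and 162, and with at least 2-fold 8, 2, 7, 2, 65 and 20. Each limit applied to both called steps, so the starting sets shrank too. Subtracting array medians gave 33 above 0 and 22 of these not called in retina; the cause was not tested. Apart from single arrays left out, the other alternatives run for the selections kept each count within 1.5 times; the 12-array block was not run for them.

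Leaving out each array in turn gave 2287 to 2457 in retina, 6226 to 7252 in RPE-attached retina, 733 to 863 in embryo, 3071 to 4019 and 4938 to 6299 for RPE-attached against bare retina in wild type and mutant, 2302 to 3454 for their difference, 873 to 986 for retina against embryo genotype effects, and 8778 to 9345 for retina against embryo. The selections ran from 159 to 337, 27 to 66, 139 to 277, 17 to 45, 303 to 362 and 406 to 518. Counts below 0 moved most without wild type retina replicate 1 (159, and 139 not called in retina). Counts above 0 fell to 27 and 32 without wild type retina replicates 1 and 2 and to 32, 30 and 28 without wild type RPE-attached replicates 1, 2 and 3; those not called in retina fell to 19 without wild type retina replicate 1, 23 without mutant retina replicate 3, and 21, 19 and 17 without wild type RPE-attached replicates 1, 2 and 3.

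No named gene or list reversed under any alternative run. Of 225 named values, the 0.001 threshold ended 26 calls and the 2-fold minimum 33. In embryos arid2 and tal1 lost their calls when only the compared groups were fitted (adjusted p 0.0666 and 0.0743). The retina against embryo difference of crybb1 was lost with trended and robust moderation (0.081), when only the compared groups were fitted (0.0777), and without each of the 5 single arrays named earlier (0.0547 to 0.0744). That of cryba4 was lost when only the compared groups were fitted (0.0544). With array weights the RPE-attached differences of crybb1 and cryba4 were lost (0.0501 and 0.0502), and on linear signal the 6 of 17 named earlier. Of 63 list calls, 28 held with an estimated correlation and 35 were lost, 61 held with fry and 62 with the block over all arrays. The block ended the call of the iridophore list for RPE-attached against bare retina in mutants (adjusted p 0.0535). Of 38 calls without an RPE-attached group, the block over the embryo and retina arrays ended 1, that of the lens list for the retina against embryo genotype effects (0.111), and leaving out the RPE-attached arrays ended that call as well (0.0506).

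Of 438 list fits that left out 1 array, 426 held and 12 lost the call. The photoreceptor list in retina was lost without mutant retina replicate 1 (adjusted p 0.083). For RPE-attached against bare retina in wild type, the synaptic list was lost without wild type retina replicate 1 (0.0755) or wild type RPE-attached replicate 2 (0.0905), and the lens list without the latter (0.0552). In mutants the muscle list was lost without mutant retina replicate 1 (0.055) or 3 (0.0649) or mutant RPE-attached replicate 3 (0.159), and the iridophore list without the last of these (0.104). For the retina against embryo genotype effects, the photoreceptor list was lost without wild type embryo replicate 3 (0.0517), mutant embryo replicate 2 (0.0951) or mutant retina replicate 1 (0.0964), and the lens list without mutant retina replicate 2 (0.0802). Weak signal limits genes under 5.15, the 30th percentile of group means.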

Other observations

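The linkage, birth order (both versions) and chaperone tests were chosen only after the result was seen; the genes named in the first paragraph were chosen after their values were seen.

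Some stress-related genes rose in mutant retina: atf5a by 2.77, atf5b by 1.69 and atf3 by 1.77, with the secreted hormone stc2a at 2.00. A hypothesis is that they may belong to a wider amino acid and unfolded protein stress response. Of 42 other genes of such a list, fixed before the test, 13 rose and 6 fell (median 0.20, camera p = 0.0492), which met the bound set beforehand narrowly and did not hold with an estimated correlation (p = 0.235). The stress transcription factor xbp1 was among those that fell. Members that rose included asparagine synthetase asns (0.79 ± 0.13), phgdh of serine synthesis (0.49 ± 0.13), chac1 (0.96 ± 0.13) and the transfer RNA synthetases aars1 (0.47 ± 0.09) and tars1 (0.42 ± 0.11). The endoplasmic reticulum chaperone genes of that list were set apart as a group only after they were seen to fall. Of these 14 genes 1 rose and 6 fell (median -0.21). Those that fell included hspa5 (-0.82 ± 0.21), hsp90b1 (-0.76 ± 0.20) and manf (-0.54 ± 0.15). The chaperones thus did not rise together in the pooled retinas. Because the group was chosen by its fall, these values do not decide about an unfolded protein response. Other stress responses stay open too, and no list of amino acid genes alone was tested.

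A uniform delay that keeps the birth order of retinal cells could lower neuronal genes. It was taken to spare genes of ganglion cells, the first type born. Among genes with a wild type retina signal above 5.15, the mean change of 20 ganglion cell genes was -1.28 and that of 41 photoreceptor, bipolar and Muller genes -0.48, a difference of -0.80 (permutation test over genes, two-sided, p = 0.00203, 100000 resamples). Dim genes cannot fall far, so the test was repeated above 7.15, where 16 and 26 genes differed by -0.78 (permutation p = 0.017). Genes are not independent replicates, and within that limit the ganglion cell list as a set was not spared. The list may also hold genes of other neurons. In wild type, gap43 and stmn2a averaged 9.93 and 10.41 in whole embryos against 9.72 and 9.58 in retina. irx4a and inab were brighter in retina (10.36 and 9.17 against 8.51 and 8.02). The lists do not separate the birth of a cell type from its later maturation, which a delay could lower too. The test therefore does not decide whether the mutant retina was delayed.

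Variants linked to the smarca4a mutation could move genes in all tissues. Of the 100 array genes nearest to smarca4a in assembly GRCz12tu, 2 were among those that moved the same way in all 3 mutant comparisons (2.00%), against 241 of 8658 others (2.78%; Fisher's exact test, one-sided, p = 0.771). Genes near smarca4a were thus not more frequent in the shared set than other genes. The test does not cover linked variants that move genes elsewhere in the genome. It therefore does not decide whether linkage is a source of the shared set.

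Lower glucocorticoid signalling could lower fkbp5 (-1.92) and klf9 (-1.81) in mutant embryos. Of 29 other genes of a glucocorticoid-responsive list, 1 rose and 1 fell (median 0.04; camera test over the list, n = 29 genes, unadjusted p = 0.574), which argues against a shift of the list as a whole.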
